A study of Mus musculus with 7 samples.

How the data were processed

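RNA was measured in pools of ovulated oocytes from C57BL/6 females of 4 weeks, 3 WT pools and 4 pools from Nlrp2-null females. Per the labels' protocols, total RNA was extracted from about 150 oocytes per pool, taken from 3 to 4 mice of the same genotype, amplified with a NuGEN kit that uses oligo d(T) and random primers, and sequenced on an Illumina HiSeq. Amplification from so little RNA means that reads are not independent molecules, so intervals from read counts cover counting error only.

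The deposited gene table holds a signal per gene symbol and pool, namely counts divided by a size factor per pool, as DESeq2 makes them, per the file headers and names. Each of its values was a whole multiple of the pool's own step within a tolerance of 0.01, so whole reads were recovered for 100% of the values. A second deposited table holds normalized counts of 18430 transcripts in 6 pools, without null 1. Only 104 of them carry an Ensembl identifier and the others no gene name, and the table was used as an alternative only. Per the submitters' processing notes the tools were TopHat2 2.0.9, HTSeq, DESeq, STAR 2.5.0a, featureCounts 1.5.0-p1, DESeq2 1.22.2 and HOMER, with the builds GRCm38 and mm10. Which of them made which table, the annotation, the filters and whether strand was used in counting are not given in the sources used here. Genes that overlap another gene, or that have near-identical copies, can therefore hold reads of both: of 123 named genes 40 have an exon that overlaps another annotated gene, 32 of them on the opposite strand and 14 on the same strand.

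The recovered reads came to 71073973, 83184707 and 96330083 in WT pools 1 to 3 and to 73291849, 76694214, 79476532 and 71795562 in null pools 1 to 4. No pair of pools within a group held counts within sampling noise of each other (chi-square per degree of freedom at least 45.4), so each pool counted as a replicate. At this depth the spread between pools, not counting error, set the precision, and the median standard error of a log2 fold change was 0.277.

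Groups were taken from the labels. The main test was limma 3.58.1 (in R 4.3.3) with a variance trend on log2(normalized count + 1), Nlrp2-null minus WT, without covariates, over the 15071 genes with a mean normalized count of at least 10. Its prior had 10.9 degrees of freedom beside 5 residual ones, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on that log2 scale, which understates the change of low genes. Gene lists were tested two-sided with camera at a preset correlation of 0.01. Where members were adjusted over a list alone, the p values were not corrected across the lists, some of which share members. Of 31 lists 30 had at least 5 tested members; the list of genes of the mitochondrial genome had 0 in the table. camera with an estimated correlation and fry, which tests whether a list moves 1 way without comparing it with other genes, were alternatives, and none of the camera calls held with an estimated correlation. A single value was compared by a two-sided exact permutation test over the 35 splits of the 7 pools, which allow p = 0.0286 at best.

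The groups, the main test, the lists, the alternatives except 2 and the rule for named genes were fixed before the data were examined. The rule took Nlrp2 and Kdm1b. It then took in each direction up to 10 called genes with the largest fold changes, a mean of at least 50 and no overlap between groups, filled to 5 by smallest p where fewer passed. Predicted genes, clones and pseudogenes were left out. It also took the 4 members of each list with the smallest p. Dek and the most abundant cumulus markers were named after their values were seen.

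Alternatives changed the pseudocount (0.5, 10), the filter (none, 100), the scaling (equal medians, quantile normalization), the limma variance model (no trend, robust, pool quality weights), added covariates (library-number series, cumulus marker mean) or a replicate block, asked for an absolute log2 fold change of at least 1, left out each pool in turn, or used edgeR 4.0.16 or DESeq2 1.42.0 on the recovered reads. Added alternatives, chosen after seeing the data, left out null 3 and null 4, or used an estimated correlation in the fit with the cumulus marker mean. Adjusted p values that DESeq2 left as NA (2080 genes) stayed NA. The labels put 2 WT and 2 null pools (WT 1, WT 2, null 1 and null 2) in a lower range of library numbers. The higher range holds 1 WT and 2 null pools (WT 3, null 3 and null 4), and the range was treated as a possible batch. Among null pools, what sets null 3 and null 4 apart can therefore not be told from that range, also in the fit that leaves both out.

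limma, edgeR, DESeq2, the list tests and the exact permutation test were tested on simulated data; the other limma settings were not. For Nlrp2-null against WT, with 15071 genes and 200 of them changed, limma found 14.9%, 49.3% and 57.6% of genes changed 1.5-, 2- and 4-fold, with 7 false calls among 88. edgeR found 14.9%, 47.8% and 57.6%, with 6 false among 86, and DESeq2 found 17.9%, 53.7% and 63.6%, with 36 false among 126. Of 30 lists over 15071 genes the 1 shifted list was called by camera at the preset correlation, by camera with an estimated correlation (adjusted p = 0.00536) and by fry (adjusted p = 0.000378), and 0 of the 29 others were. The exact permutation test of the list mean gave p = 0.0286, its smallest, for the shifted list, and an unadjusted p under 0.05 for 2 of the 29 others. The simulated genes were drawn independently of each other. These list results therefore do not cover false calls in lists whose members move together. Nor do the counts of false gene calls cover differences between pools that move many genes together. The real cumulus and ribosomal lists had estimated correlations of 0.323 and 0.777.

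Coordinates come from a GENCODE annotation of GRCm38. Of 18951 symbols 18214 were matched by symbol and 524 by an older symbol, 213 were not matched, and 35 were matched to several loci and not placed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6).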

Results

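RNA was sequenced from pools of ovulated mouse oocytes that lacked Nlrp2 and from wild-type (WT) pools. NLRP2 is a maternal effect protein of the NLR family that is stored in the egg. The series asks whether its loss alters the oocyte transcriptome, and its title names the histone demethylase KDM1B. The labels describe C57BL/6 females of 4 weeks, whose cumulus-oocyte complexes were taken from the oviduct and stripped of cumulus cells with hyaluronidase. Each pool held about 150 oocytes from 3 to 4 mice of 1 genotype, and there were 3 WT and 4 Nlrp2-null pools. Pools were therefore treated as separate collections of animals. The gene table held 18951 symbols, and 71073973 to 96330083 reads per pool stood behind its normalized counts. Each pool had a value above 0 for between 15958 and 16886 genes, and its 10 highest genes took 6.58% to 7.51% of the total. The first principal component carried 27.8% of the variance and did not part the genotypes. It set WT 2 (69.1), null 1 (49.5) and WT 3 (34.9) against null 3 (-58.8) and null 4 (-96.7), with WT 1 (-1.18) and null 2 (3.02) between them.

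Nlrp2 transcripts were almost gone from every null pool. Nlrp2 lies on chromosome 7 (5298547 to 5351035, minus strand, GRCm38). Its normalized counts were 15527, 20130 and 16792 in the WT pools and 107, 8.19, 1.96 and 63.8 in null pools 1 to 4. The null values were 0.614%, 0.0469%, 0.0112% and 0.365% of the WT mean. They rest on 99, 8, 2 and 61 reads, with exact 95% Poisson intervals of 80.5 to 121, 3.45 to 15.8, 0.242 to 7.22 and 46.7 to 78.4 reads, which cover counting error only. The log2 fold change was -9.70 (SE 0.851, limma adjusted p = 6.98e-05, lower in 4 of 4 null pools). The labels do not say which exons the null allele lacks, and the value sums reads over the whole gene. limma without a variance trend (adjusted p = 0.316) and its robust version (adjusted p = 0.147) did not call Nlrp2.

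Beside Nlrp2, 9 genes passed the test, 8 higher and 1 lower in null pools. Obox3, an oocyte-expressed homeobox gene on chromosome 7, rose from 119 ± 14.7 (SD, n = 3) to 670 ± 243 (SD, n = 4) normalized counts. Cldn34d, a claudin gene on chromosome X, rose from 259 ± 102 to 1071 ± 54.1. Ceacam2, a cell adhesion gene on chromosome 7, and Cdo1, the cysteine dioxygenase gene that starts cysteine breakdown, each came to 2.00 times the WT level. Ceacam2 went from 3216 ± 336 to 6462 ± 995 and Cdo1 from 14169 ± 3191 to 28211 ± 5344. The guidance receptor gene Robo1 rose 1.83-fold, from 6040 ± 257 to 11046 ± 781, and the semaphorin gene Sema6a rose 1.83-fold, from 1807 ± 87.4 to 3303 ± 238. Dcaf5, a substrate receptor of CUL4 ubiquitin ligases, rose 1.62-fold, and Ctnnd1, which encodes the cadherin partner p120-catenin, rose 1.51-fold, from 19295 ± 740 to 29142 ± 1495. Tex15, a germ cell gene needed for meiotic recombination and transposon silencing in the testis, fell from 13596 ± 1578 to 8228 ± 1277, which is 0.603 times the WT level. Adjusted p values from limma ran from 0.00106 for Robo1 to 0.0237 for Tex15, and in each of these genes all 4 null pools lay on the same side of all 3 WT pools.

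**Figure D1:**
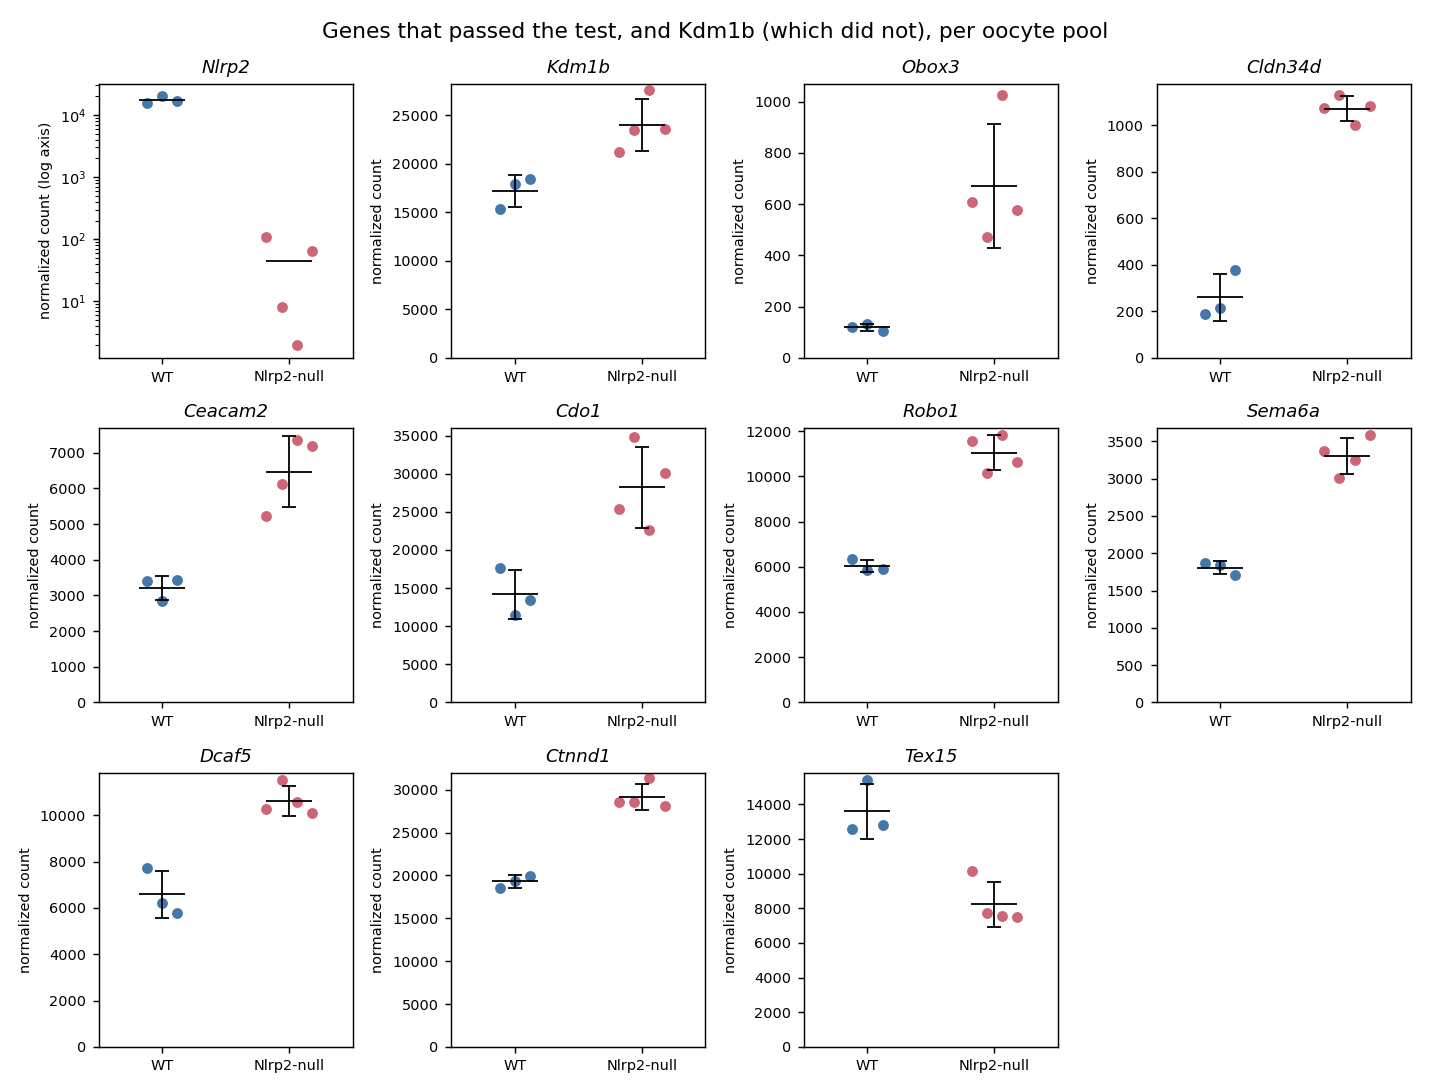
Normalized counts of the 10 genes that passed the test and of Kdm1b, which did not; points are pools (3 WT, 4 Nlrp2-null), long bars are means and error bars are SD. The Nlrp2 axis is logarithmic and carries no SD, and the null pools lie between 1.96 and 107 there against 15527 to 20130 in WT.

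These 10 calls came from limma on log2(normalized count + 1) over 15071 genes at a Benjamini-Hochberg adjusted p under 0.05, and 1538 genes had an unadjusted p under 0.05, 795 higher and 743 lower. On recovered whole reads edgeR called 7 genes, all among the 10, and not Cdo1, Dcaf5 (adjusted p = 0.0535 each) or Tex15 (adjusted p = 0.0635). DESeq2 called 200 (115 higher, 85 lower), among them all 10, and all 200 had the same sign and an unadjusted p under 0.05 in limma. Both tools used the same 7 pools, so this is not independent support. In the simulated data, where genes were drawn independently of each other, 36 of 126 DESeq2 calls were false. Leaving out a pool moved the limma count to between 2 (without null 3) and 16 (without null 1), and only Nlrp2 and Robo1 were called in each of the 7 such fits. Ctnnd1 and Cldn34d were called in 5 of them, Obox3 and Ceacam2 in 4, Sema6a and Cdo1 in 3, and Dcaf5 in 2 (without WT 1 and without null 1). Tex15, the only lower gene beside Nlrp2, was called in 1 of them, without null 1 (adjusted p = 0.00410), and had adjusted p values from 0.0524 (without WT 1) to 0.380 (without WT 2) in the other 6. Without null 3 and null 4 no gene was called and 1080 had an unadjusted p under 0.05. Obox3, Cldn34d and Ceacam2 have relatives that can share reads where sequences are near-identical, which was not tested. Ctnnd1 overlaps a read-through gene on its own strand. The levels of Obox3, Cldn34d, Ceacam2 and Ctnnd1 are therefore uncertain.

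Too few lower genes passed to fill the list of named genes, so 3 more were taken by smallest p. They did not pass. Plekhb1 was at 1233 ± 30.6 in WT and 578 ± 110 in null pools (log2 fold change -1.11, SE 0.212, limma adjusted p = 0.0817). Zkscan8, a zinc finger gene, was at 5716 ± 111 and 3937 ± 150 (-0.54, SE 0.106, limma adjusted p = 0.0826). Atad2, a bromodomain ATPase gene, was at 7972 ± 222 and 5291 ± 714 (-0.60, SE 0.119, limma adjusted p = 0.0826). DESeq2 called all 3 of them.

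Kdm1b, which encodes the histone H3 lysine 4 demethylase that is needed to set maternal DNA methylation imprints in growing oocytes, had higher values in null pools but did not pass over all genes. It lies on chromosome 13 (47043499 to 47085279, plus strand). WT pools held 15294, 17938 and 18373 normalized counts and null pools 21249, 23445, 27626 and 23602. The means were 17202 ± 1667 and 23981 ± 2657, a fold of 1.39 (95% interval 1.20 to 1.61, log2 fold change 0.48, SE 0.101). All 4 null pools lay above all 3 WT pools. The adjusted p was 0.1004 in limma and 0.133 in edgeR, neither of which called it, and 0.0016 in DESeq2, which did; pool quality weights in limma also brought it past the threshold (adjusted p = 0.0456). Over 22 alternative fits the log2 fold change stayed between 0.38 and 0.53 while its adjusted p ran from 0.0016 to 0.576. Adjusted over the list alone, among 22 tested histone lysine demethylases, its p was 0.00495 in limma. Because the study's title names KDM1B, that value is not independent evidence. Within the lower range of library numbers the log2 difference was 0.43 (2 WT, 2 null pools), and within the higher range it was 0.47 (1 WT, 2 null pools). With that range as a covariate it was 0.45 (limma adjusted p = 0.132). The end of Kdm1b overlaps the gene Dek on the opposite strand, and whether strand was used in counting is not given in the sources used here. Dek stood at 29407 ± 1330 in WT and 25814 ± 1037 in null pools (log2 fold change -0.19, SE 0.0787, limma adjusted p = 0.437).

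No other histone lysine demethylase passed over the list alone in limma or over all genes in DESeq2. Kdm4c had a log2 fold change of 1.30 (SE 0.458) and Kdm5a of 0.65 (SE 0.247), and the list as a whole was not shifted (camera adjusted p = 0.111). Genes of DNA methylation, demethylation and imprint maintenance were shifted upward as a list: 19 of 25 tested members had positive fold changes, with a median of 0.14 (camera adjusted p = 0.0281). With an estimated correlation the adjusted p was 0.664. The call was also lost with equal medians in every pool (median 0.08, adjusted p = 0.130), with pool quality weights (adjusted p = 0.0691), without WT 1 (0.0871), WT 3 (0.0544), null 3 (0.0904) or null 4 (0.0712), and without both null 3 and null 4 (0.277). None of its members passed over all genes in limma (3 had an unadjusted p under 0.05) or edgeR, and DESeq2 called 2, Kdm1b and Tet2 (adjusted p = 0.0381). Adjusted over the list alone, the same 2 passed in limma: Kdm1b itself and Tet2, an enzyme that oxidizes 5-methylcytosine, at 1342 ± 85.4 in WT and 1915 ± 33.1 in null pools. Among histone acetyltransferases and deacetylases 1 of 31 passed over the list alone, the deacetylase gene Hdac5, which was low in both groups (21.7 ± 4.80 and 154 ± 47.2) and which DESeq2 called over all genes (adjusted p = 0.000888, limma adjusted p = 0.119), and the list was not shifted (camera adjusted p = 0.709). The other chromatin lists had no such member. They were 35 histone methyltransferases (camera adjusted p = 0.964; Kmt2e at 0.42, SE 0.132), 32 Polycomb genes (camera adjusted p = 0.703; Ezh2 at -0.28, SE 0.0994), and 38 chromatin remodelling genes (camera adjusted p = 0.964; Arid2 at 0.23, SE 0.0853). Of 43 tested imprinted genes none passed over the list alone in limma (6 had an unadjusted p under 0.05) or over all genes in DESeq2 (camera adjusted p = 0.167), with Peg3 at a log2 fold change of 0.39 (SE 0.149) and Grb10 at 0.31 (SE 0.129).

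Partners and relatives of NLRP2 showed no call. None of 12 tested subcortical maternal complex genes passed over all genes or over the list alone in limma (camera adjusted p = 0.365, median log2 fold change -0.02); 1 had an unadjusted p under 0.05 and DESeq2 called 0. Tle6, a core member, was at 13720 ± 780 in WT and 11266 ± 1518 in null pools (-0.29, SE 0.108), and Padi6, which is needed for the cytoplasmic lattices, was at 55812 ± 3083 and 50234 ± 3616 (-0.15, SE 0.0802). None of 16 other NLRP genes passed in limma or DESeq2 (1 with an unadjusted p under 0.05 in limma, camera adjusted p = 0.692). Nlrp5, also called Mater, stood at 123315 ± 6711 in WT and 133630 ± 10648 in null pools, and Nlrp4c at 1807 ± 247 and 1321 ± 471. Of 46 maternal effect genes only Kdm1b passed over the list alone in limma or over all genes in DESeq2, and the list was not shifted (camera adjusted p = 0.429). With the cumulus marker mean as a covariate the maternal effect list was called upward (median 0.08, camera adjusted p = 0.00956), and with an estimated correlation in that fit the adjusted p was 0.447.

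Oocyte identity genes were mixed. Of 46 tested members Obox3 passed over all genes in limma, and Obox3 upward and Dazl downward passed over the list alone and were called by DESeq2; the list was not shifted (camera adjusted p = 0.848). With the cumulus marker mean as a covariate its median went from 0.04 to 0.13 and it was called upward (camera adjusted p = 0.000567), and with an estimated correlation in that fit the adjusted p was 0.447. Dazl, an RNA-binding translational activator of germ cells, was at 42830 ± 3705 in WT and 32252 ± 1463 in null pools (log2 fold change -0.41, SE 0.082, limma adjusted p = 0.0826 over all genes and 0.00334 over the list alone, DESeq2 adjusted p = 0.000593). It was also the only 1 of 67 mRNA storage and decay genes to pass over that list alone in limma (camera adjusted p = 0.964), where DESeq2 called 2 others over all genes, Edc3 with higher and Rqcd1 with lower values in null pools. In the meiotic maturation list 3 of 57 members passed over the list alone, without correction across lists, each with lower values in null pools. Ccnb3, the cyclin that promotes anaphase of meiosis I, was at 10200 ± 732 and 7526 ± 317 (-0.44, SE 0.0963), Btrc, a substrate receptor of SCF ubiquitin ligases, had -0.40 (SE 0.109) and Ccne1, cyclin E1, had -1.44 (SE 0.401). In the spindle and kinetochore list 2 of 74 did so, also lower: Haus3, an augmin subunit, at 7771 ± 75.1 and 5233 ± 776, and Casc5, the kinetochore scaffold also called Knl1, at 12241 ± 263 and 9617 ± 445. Neither list was shifted in the main fit (camera adjusted p = 0.27 and 0.111). The spindle list was called downward without WT 1 (camera adjusted p = 0.00543), null 1 (0.0374) or null 2 (0.0400), and in no other alternative. None of the 5 genes passed over all genes in limma or edgeR. DESeq2 called 4 of them over all genes, Ccnb3 (adjusted p = 0.00157), Haus3 (0.00131), Casc5 (0.00958) and Btrc (0.0379), and not Ccne1 (0.0525). Haus3 overlaps Poln on its own strand.

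Of 43 heat shock and unfolded protein response genes none passed over all genes in limma (8 had an unadjusted p under 0.05) or edgeR and 4 passed over the list alone in limma. DESeq2 called 2 over all genes, Hspa5 (adjusted p = 0.00599) and Hsp90ab1 (adjusted p = 0.0405). The endoplasmic reticulum chaperone Hspa5 was at 18164 ± 1079 in WT and 23514 ± 1681 in null pools (log2 fold change 0.37, SE 0.0873), Hsp90b1 at 69686 ± 4984 and 83265 ± 3568, and the cytosolic Hsp90ab1 at 27440 ± 1030 and 32686 ± 407. Hspa4 went the other way, at 27987 ± 2704 and 22345 ± 2262. The list was not shifted (camera adjusted p = 0.111). Among 44 cholesterol and lipid synthesis genes Scd2, a stearoyl-CoA desaturase (2576 ± 1446 and 5558 ± 2146), and Cyp51, the lanosterol demethylase (597 ± 22.3 and 1247 ± 466), passed over the list alone in limma, again with no shift of the list (camera adjusted p = 0.111). Neither passed over all genes in limma, and DESeq2 called Cyp51 (adjusted p = 0.0140) and not Scd2 (0.327). Both genes were highest in null 3 and null 4, the pools with the highest cumulus marker means and the null pools of the higher range of library numbers. Scd2 overlapped between groups (4220 in WT 1, 3332 in null 1). The log2 fold changes were 1.17 for Scd2 and 0.98 for Cyp51, and 0.54 and 0.66 with the cumulus marker mean as a covariate, where the list median went from 0.16 to -0.01. The lipid list was called upward without WT 1 (median 0.18, camera adjusted p = 0.0183) and with pool quality weights (0.13, 0.0485), and in no other alternative.

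Markers of cumulus and granulosa cells, the somatic cells removed before sequencing, were shifted upward in null pools. Of 39 tested markers 34 had positive fold changes, with a median of 0.55 and a camera adjusted p of 1.82e-05; with an estimated correlation the adjusted p was 0.85. None passed over all genes in limma (6 had an unadjusted p under 0.05) or edgeR, and DESeq2 called 1, Inhbb (adjusted p = 6.6e-06). Over the list alone 2 passed in limma, Inhbb, an inhibin subunit gene (19.4 ± 14.5 in WT, 340 ± 346 in null pools), and Fst, the activin antagonist follistatin (1156 ± 434 and 2671 ± 1244). The marker mean on the log2 scale was 9.03, 7.94 and 8.22 in the WT pools and 8.46, 8.72, 9.43 and 10.001 in null pools 1 to 4, so that 2 null pools lay below WT 1. The difference of 0.75 gave p = 0.2 in a two-sided exact permutation test, where 35 splits allow 0.0286 at best. The median was 0.93 without null 1 (camera adjusted p = 1.5e-08), 0.84 without WT 1 (camera adjusted p = 2.11e-09) and 0.29 without WT 2 (camera adjusted p = 0.0351). The shift was not called without null 4 (median 0.24, adjusted p = 0.0664), and without null 3 and null 4 the median was 0.04 (adjusted p = 0.600). Among the 6 most abundant markers the WT and null means were 84017 and 75532 for Rgs2, 16881 and 19158 for Serpine2, 4443 and 4183 for Cyp19a1 and 5376 and 7082 for Vcan. Oviduct, stroma and vessel markers had a median log2 fold change of 0.83 over 24 genes without a call (camera adjusted p = 0.124), and their mean was 8.04 in null 4 against 5.20 to 6.19 in the other pools. Blood and immune markers showed none either (15 tested, camera adjusted p = 0.794).

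Ribosomal protein genes moved with the cumulus markers from pool to pool. Of 77 tested genes 66 had positive fold changes (median 0.32, camera adjusted p = 1.82e-05), and with an estimated correlation the adjusted p was 0.936. None passed over all genes or over the list alone in limma (8 had an unadjusted p under 0.05), and DESeq2 called 0. Rps26 was at 390 ± 178 in WT and 858 ± 301 in null pools, and Rps15a at 8810 ± 1820 and 6735 ± 742. The list mean was 10.38, 9.30 and 9.82 in the WT pools and 9.52, 9.93, 10.45 and 10.71 in null pools 1 to 4 (difference 0.32, two-sided exact permutation p = 0.457). The median was 0.57 without WT 1 (camera adjusted p = 1.51e-14) and 0.49 without null 1 (camera adjusted p = 9.99e-14). The list was not called without WT 2 (median 0.05, adjusted p = 0.605), null 4 (0.13, adjusted p = 0.360) or both null 3 and null 4 (-0.06, adjusted p = 0.456). With the cumulus marker mean as a covariate the median was -0.25 (camera adjusted p = 1.96e-07), and with an estimated correlation in that fit the adjusted p was 0.564. Over the 7 pools the ribosomal and cumulus means had a Pearson r of 0.941 (exact permutation p = 0.00218) and a Spearman rho of 0.964 (exact permutation p = 0.00278). Without null 4 and WT 2, the pools farthest from the median cumulus mean, r was 0.869. This was the only such correlation between list means computed, and each range of library numbers holds too few pools to repeat it.

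**Figure D2:**
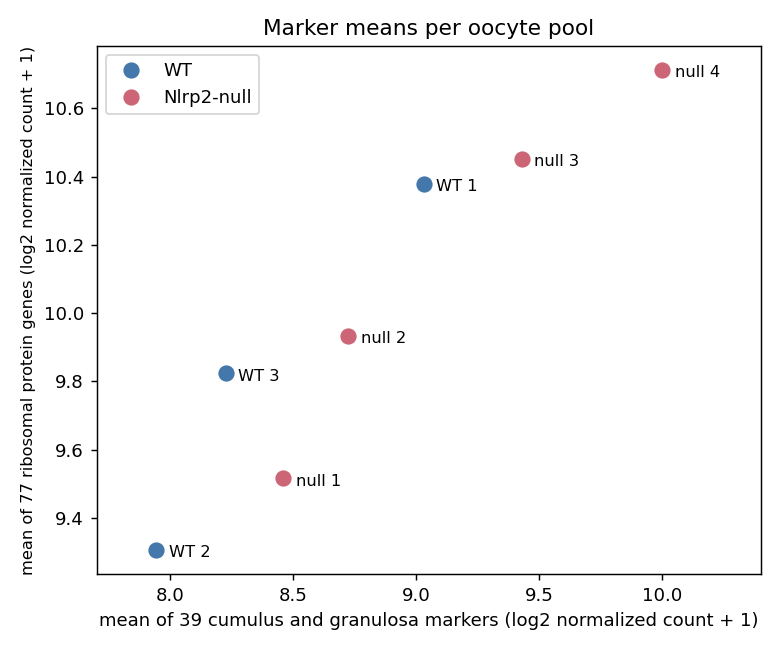
Mean log2(normalized count + 1) of 77 ribosomal protein genes (vertical axis) against that of 39 cumulus and granulosa markers (horizontal axis); each point is a pool, labelled by genotype and number. Both axes start above 0, and the pools run from WT 2 (7.94 and 9.30) to null 4 (10.001 and 10.71) with both genotypes mixed.

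The remaining lists had no member past the threshold in limma, over all genes or over the list alone, and no shift by camera; each had 1 to 6 members with an unadjusted p under 0.05. DESeq2 called 1 of their members, the redox gene Nqo1 (adjusted p = 0.0497, limma adjusted p = 0.242). Lower medians were found for 28 small RNA pathway genes (-0.12, adjusted p = 0.111), among them Marf1 at -0.26 (SE 0.0808), for 43 proteasome genes (-0.07, adjusted p = 0.355), and for 39 cohesin and meiotic chromosome genes (-0.07, adjusted p = 0.5), among them Smc1b at -0.35 (SE 0.116). Higher medians were found for 42 redox genes (0.17, adjusted p = 0.111), among them Nqo1 at 0.66 (SE 0.189), and for 77 nuclear genes of oxidative phosphorylation (0.16, adjusted p = 0.528). The redox list was called upward without WT 1 (median 0.26, camera adjusted p = 0.00372) and with pool quality weights (0.19, 0.0485), and its median was 0.03 without WT 2. The small RNA list was called downward without null 1 (median -0.15, camera adjusted p = 0.0374). The redox and oxidative phosphorylation medians were 0.01 and -0.17 with the cumulus marker mean as a covariate. In that fit the imprinted list had a median of -0.06, the oviduct and NF-kappaB lists each -0.09, the other NLRP list 0.11, and the small RNA, cohesin and spindle lists each 0.04, none of them called. Egg activation (37 genes, adjusted p = 0.964), cortical cytoskeleton (51, adjusted p = 0.5), apoptosis and p53 (36, adjusted p = 0.964), NF-kappaB and inflammasome (37, adjusted p = 0.964) and the first zygotic wave (18, adjusted p = 0.964) had medians within 0.1 of 0. In the proteasome, other NLRP, Polycomb, histone acetylation, histone methyltransferase and chromatin remodelling lists the median was negative and the mean positive. The camera direction followed the median in the proteasome, other NLRP and Polycomb lists and the mean in the others. In the egg activation and p53 lists median and mean were positive and the camera direction was down.

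**Figure D3:**
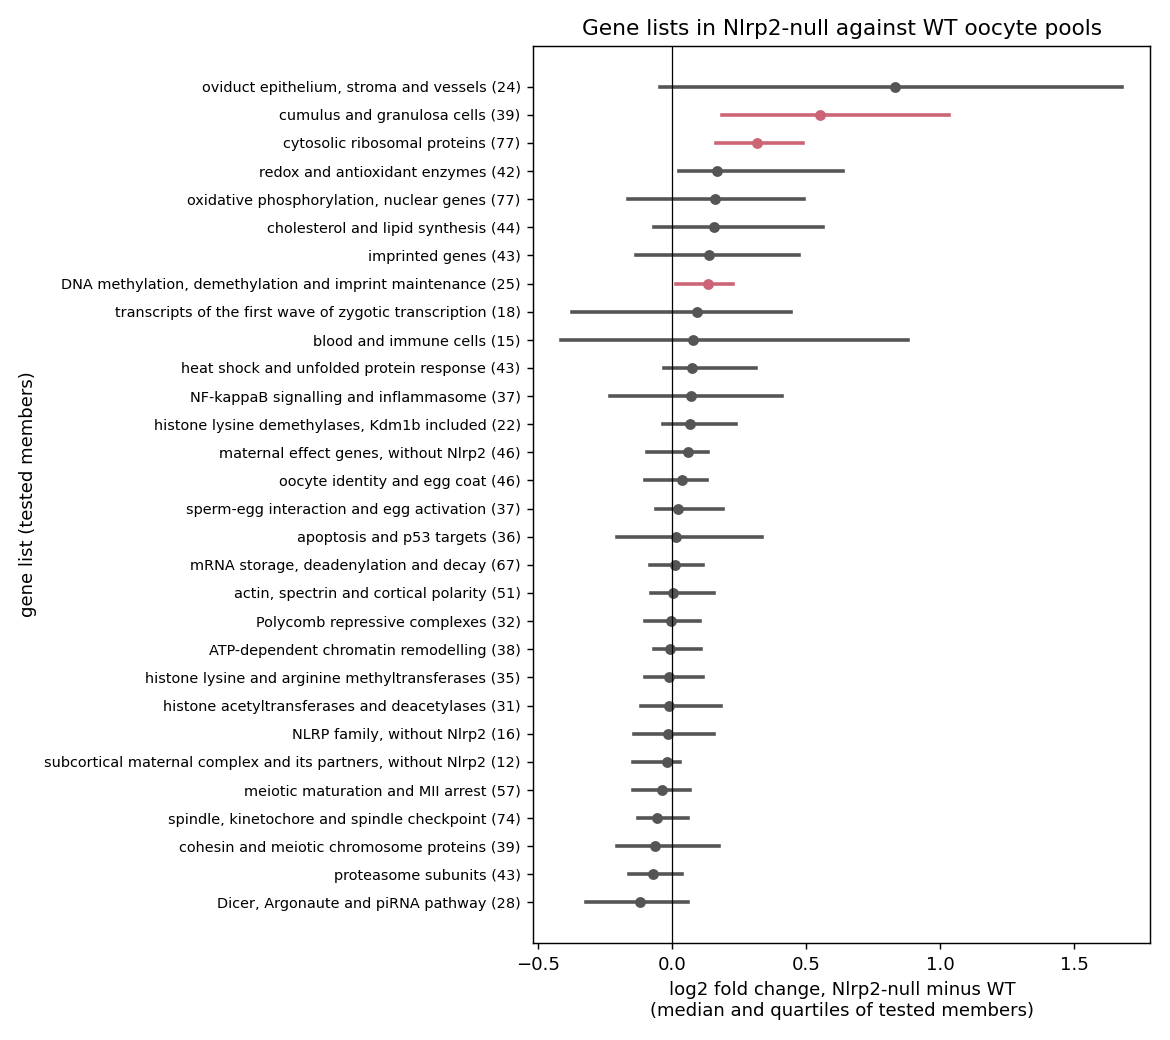
Log2 fold change (Nlrp2-null minus WT, horizontal axis) of the tested members of 30 gene lists; dots are medians and lines run between the quartiles. Red marks the 3 lists with a camera adjusted p under 0.05 at the preset correlation, none of which kept it with an estimated correlation.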

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

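The 2 tests of the cumulus markers were chosen only after the result was seen, as was the estimated correlation in the fit with the cumulus covariate. The other tests here were set before they were run, but the patterns they address had already been seen. In 11 of 153 sets of 4 null values (123 genes and 30 list means), the gap between a pool and its nearest neighbour took up more of the whole range than Dixon's 95% critical value for 4 samples allows. Chance gives this in about 1 of 20 sets. Null 3 stood apart in Ctnnd1 (31354 against 28062 to 28619, ratio 0.831), Kdm2b (21434 against 23689 to 23738, ratio 0.979), Smyd2 (214 against 337 to 354, ratio 0.877), Uchl5 (1117 against 1562 to 1647, ratio 0.839) and Lyz1 (215 against 11.5 to 38.9, ratio 0.865). Null 4 stood apart in Mael (4220 against 3834 to 3870, ratio 0.906), Ereg (208 against 22.6 to 41.2, ratio 0.900), Krt8 (707 against 137 to 228, ratio 0.840) and the mean of the oviduct, stroma and vessel list (8.04 against 5.62 to 5.86 on the log2 scale, ratio 0.900). Null 1 stood apart in Tex15 (10138 against 7503 to 7744, ratio 0.908) and null 2 in Hdac5 (84.0 against 173 to 185, ratio 0.882). Values are normalized counts except for the list mean.

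The first pattern is the set of 10 genes that limma called, for whose number a chance arrangement of the pools cannot be excluded. Of the 35 splits of the 7 pools 3, the real one among them, gave at least 10 calls, the others of these giving 173 and 112. Most other splits gave 0, and the split that set null 2, null 3 and null 4 apart gave 7. For DESeq2 3 splits, the real one among them, gave at least its 200 calls, the highest other giving 463. This count does not bear on Nlrp2, the targeted gene, which was at 0.0112% to 0.614% of the WT mean in null pools. Counts many times the real one point to a structure of the samples: the 2 splits concerned set apart the 3 pools with the lowest and the 3 with the highest cumulus marker means, and the split along library numbers gave 0 limma calls and 9 by DESeq2. With the cumulus marker mean as a covariate limma called 11 genes and kept 7 of the 10, which argues against cumulus content as the whole cause for those 7, while Sema6a went from 0.87 (SE 0.130) to 0.81 (SE 0.155), Dcaf5 from 0.70 (SE 0.111) to 0.65 (SE 0.128) and Tex15 from -0.73 (SE 0.1196) to -0.57 (SE 0.1203), the last with a smaller fold and the others mainly with a larger error; with the library-number series as a covariate all 10 were kept. A chromosome 7 segment carried along with the null allele could raise or lower genes near Nlrp2. Of the 9 other called genes 1 (Obox3) lay within 20 Mb (11.1%, exact 95% interval up to 48.2%), against 1.62% of the other tested genes (Fisher p = 0.137). Of 197 placed genes called by DESeq2 beside Nlrp2 2 lay there, Obox3 and Zfp772 (1.02% against 1.63%, Fisher p = 0.774). These values and the 7 of 9 genes on other chromosomes argue against the segment for most of the calls. It stays open for Obox3, for Zfp772 (log2 fold change 2.39, limma adjusted p = 0.230, DESeq2 adjusted p = 0.00158) and for Ceacam2. Ceacam2 lies just outside that window (2 of 9 on chromosome 7, 22.2%, exact interval up to 60.0%, against 7.61%, Fisher p = 0.146). An effect of Nlrp2 loss also stays open, as do, for Obox3, Cldn34d and Ceacam2, reads shared with relatives, which were not tested.

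The second pattern is the higher level of cumulus and granulosa markers in null pools. Cumulus cells that remained in some pools would make the markers rise and fall together within each genotype, and their estimated correlation with group means removed was 0.323 (0.327 within WT, 0.349 within null pools), against at most 0.0834 in 1000 random lists, as that source would need, but lists of oocyte genes also passed 0.1 (subcortical maternal complex 0.352, spindle 0.174, oocyte identity 0.134, other NLRP 0.1203), so that value does not set remaining cells apart from other differences between pools. Of 45 markers 39 were tested, 1 is also in another list, 32 had a value of at least 10 in every pool so that oocytes may express some of them, and hyaluronidase would remove most such cells; the most abundant were Rgs2 (84017 in WT, 75532 in null), Serpine2, Hsd3b1 (11663 and 14055), Nr5a2 (6377 and 6831), Vcan and Cyp19a1. Against a change in the null oocytes themselves, 2 null pools lay below the highest WT pool and the exact permutation p was 0.2, which cannot decide it. At least 3 shifted lists came from 19 of 35 splits, the highest other giving 15, so chance cannot be excluded for the count of lists.

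The third pattern is the higher median of the ribosomal protein genes. Transcript length may enter, since their median length is 637 against 1502 bases, but removing the trend with length left the median at 0.29 (quartiles 0.12 and 0.45, before 0.32), which argues against length as the whole cause. Remaining cumulus cells would tie the list to the cumulus markers, and r was 0.941 over the 7 pools. The redox list mean also ordered the pools as the cumulus mean did, while the oocyte identity mean did not. The redox mean was 9.27, 8.67 and 8.87 in WT pools 1 to 3 and 9.02, 9.22, 9.38 and 9.50 in null pools 1 to 4. Such a tie is therefore not particular to ribosomal genes and does not set remaining cells apart from other differences between pools. With the cumulus marker mean as a covariate the ribosomal median was -0.25 (camera adjusted p = 1.96e-07, and 0.564 with an estimated correlation), so no rise in null pools was left once the markers were accounted for. Together with the exact permutation p of 0.457 for the list mean, these values leave a genotype effect open in either direction, and RNA quality was not tested.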

How the results depend on the processing

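The fit without null 3 and null 4, and the estimated correlation in the fit with the cumulus covariate, were chosen after seeing the data, and the other alternatives were planned; where no reason is given the cause was not tested. The 10 limma calls (8 higher, 2 lower) became 0 without a variance trend (1252 genes at an unadjusted p under 0.05), 0 without null 3 and null 4 (1080), 6 with equal medians (5 higher, 1 lower), 68 with pool quality weights (34 higher, 34 lower), 200 by DESeq2 (115 higher, 85 lower), and 3 with an absolute log2 fold change of at least 1 (2 higher, 1 lower). The second deposited table gave 0 calls by limma among 18339 transcripts (1488 at an unadjusted p under 0.05, smallest adjusted p = 0.529). Its identifiers name no gene except for 104 Ensembl transcripts, of which 98 were matched. Of these 0 matched Nlrp2, Kdm1b or another named gene and 5 a list member, at most 1 per list, so no list was tested. With the same pools, without null 1, the gene table called Nlrp2 (log2 fold change -10.49, limma adjusted p = 3.73e-06). The second table thus did not show the loss of the targeted gene, and its 0 calls cannot test the 10 gene calls. Lower calls came to 1 without a filter, with the robust fit and with edgeR, which called 7 genes. Leaving out a pool gave 12 calls without WT 1, 4 without WT 2, 5 without WT 3, 16 without null 1, 8 without null 2, 2 without null 3 and 4 without null 4 (1 to 11 higher, 1 to 5 lower). With fewer pools the test has less power, but the count went both ways. The other settings, the replicate block below excepted, gave 7 to 13 calls, and with the library-number series as a covariate all 10 genes were kept.

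Nlrp2 stayed lower everywhere, with log2 fold changes from -10.49 to -8.59 (-10.49 to -8.76 leaving out a pool). It was not called without a trend (-9.70, limma adjusted p = 0.316), with the robust fit (-9.70, limma adjusted p = 0.147) or without null 3 and null 4 (-9.11, limma adjusted p = 0.133). Kdm1b passed only with quality weights (0.42, limma adjusted p = 0.0456) and DESeq2 (0.48, adjusted p = 0.0016), in a range from 0.0016 to 0.576, and its log2 fold change lay between 0.40 and 0.53 leaving out a pool. The 9 other called genes kept direction in 198 of 198 values and the threshold in 128. Their values did not overlap between groups, so most of these settings could not turn their direction. Of 2450 values of 112 uncalled named genes 29 passed and 0 changed direction. These genes were named by smallest p, which favours a kept direction.

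The 3 shifted lists became 5 without WT 1 and without null 1, 0 without null 4, 0 without null 3 and null 4, 0 with an estimated correlation, with or without the cumulus marker mean as a covariate, and 0 by fry. The ribosomal median turned to -0.25 with the cumulus marker mean as a covariate and to -0.064 without null 3 and null 4. Of 621 values of the 27 other lists 73 had the other direction by the test, none past the threshold, and 10 passed in the same direction.

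Replicate numbers did not pair the pools: same-numbered pools had correlations of -0.16, 0.02 and -0.01, and WT 2 correlated best with null 1. With the replicate number as a block, over replicates 1 to 3, 1 gene was called (0 higher, 1 lower) and 2 lists.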

Other observations

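The F-box cluster below was chosen only after its values were seen, as was the choice of transcripts. Oocyte-expressed F-box genes of the Fbxw13 to Fbxw28 group lie side by side on chromosome 9 (109139447 to 109790670, GRCm38), and all 13 tested there had lower values in null pools, with a median log2 fold change of -0.34. Fbxw28 was at 43943 ± 4614 (SD, n = 3) in WT and 31769 ± 4163 (SD, n = 4) in null pools, Fbxw14 at 18368 ± 1794 and 13508 ± 1581, and Fbxw22 at 21458 ± 2721 and 16275 ± 1797. limma called 0 of them over all genes (smallest adjusted p = 0.111, 11 at an unadjusted p under 0.05), edgeR gave the same 13 directions and DESeq2 called 4. The cluster mean was 13.7 ± 0.119 in WT and 13.3 ± 0.166 in null pools on the log2 scale (two-sided exact permutation p = 0.0857), and 3 of 4 null pools lay below every WT pool. All 13 were also lower with equal medians and with quantile normalization, and 12 with the cumulus marker mean as a covariate (median -0.23). Neighbouring relatives of this kind can share reads where their sequences are alike, which was not tested, so they cannot be counted as 13 independent values. Fbxw17, on chromosome 13, had a log2 fold change of 0.30.

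In the second deposited table, which lacks null 1, the transcripts with the smallest p in each direction did not pass (limma adjusted p = 0.529 for each). CUFF.49527.1 was at 14.7, 9.93 and 6.58 normalized counts in WT pools 1 to 3 and at 151, 282 and 177 in null pools 2 to 4, and TCONS_00011463 had means of 220 and 863. TCONS_00005670 had means of 179 and 3.41. TCONS_00105927 had a mean of 108 in WT pools and was listed at 0 in each of the 3 null pools.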
